A study of Mus musculus with 15 samples.

How the data were processed

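Total RNA from mouse embryonic stem cells was labelled with an Affymetrix whole transcript kit and hybridised to 1-colour arrays, 1 array per sample, per the labels' protocols. The 15 samples formed 5 groups of 3, taken from the sample titles: scrambled shRNA, Tet1 shRNA 4 and Tet1 shRNA 5 in the Tet1 set of 9 arrays, and scrambled shRNA and Sin3A shRNA in the Sin3A set of 6 arrays. Nothing in the labels says that the 3 arrays of a group came from separate cultures, so p-values measure only the spread between these arrays, which may be technical.

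The deposited table held log2 expression values for 21212 probe sets, each named by an Entrez gene number. Per the submitters' processing notes, the tools affy, RMA and limma were used, with no version or order given. RMA corrects the background, quantile-normalizes the arrays and summarises each probe set, and which of these steps were run with which settings is not given in the sources used here. The column means were 7.08 to 7.11 in the Tet1 set and 8.09 in all 6 arrays of the Sin3A set, so both sets appear to have been normalized separately, and levels were compared only within a set. In the Tet1 set 10415 probe sets (49.1%) held the same value in at least 2 of the 9 arrays, and the tie lay at the median of the 9 arrays in 94.5% of them. No such tie occurred in the Sin3A set. Median polish, the summary step of RMA, can give such ties, and the origin of the difference between the sets is not given in the sources used here.

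Gene names came from a table that pairs probe sets with the platform annotation. It gave 1 symbol for 18786 probe sets, several for 6 and none for 2420. Of the 18792 annotated entries, 18775 were found in a RefSeq gene table (assembly GRCm38.p6) and had the same symbol there. No genome build is named in the sources used here, so no coordinates are given. Where a gene had more than 1 probe set, the one with the highest mean over all arrays was kept, which left 18784 genes.

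Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), and p-values were adjusted by the Benjamini-Hochberg method over all 21212 probe sets, with a threshold of 0.05. The 9 arrays of the Tet1 set entered 1 fit with 3 group means, which gave each Tet1 shRNA against scrambled and Tet1 shRNA 5 against Tet1 shRNA 4. The 6 arrays of the Sin3A set entered a fit of their own. A fit of all 15 arrays with 5 group means gave the difference between the mean Tet1 effect and the Sin3A effect. A probe set was called for both Tet1 shRNAs when it passed the threshold for both with the same sign. The overlap with the Sin3A calls was tested per direction with Fisher's exact test, and probe sets are not independent of each other, so these p-values only describe the overlap. The Sin3A calls were also shuffled 1000 times within 50 bins of mean signal level, and the counts per direction from these shuffles were added after the overlap had been seen. Both Tet1 comparisons use the same 3 scrambled arrays, which makes their chance values alike, and this was simulated 20 times with unchanged groups.

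In total 24 gene lists were set. Of their 667 symbols 608 were matched, and after synonyms were merged the lists held 600 members. The lists were naive pluripotency, formative and early epiblast, primitive endoderm, trophectoderm and placenta, mesendoderm and primitive streak, neuroectoderm, Nodal signalling, germline, 2-cell-like genes, DNA methylation machinery, SIN3 complex, Polycomb components, Hox genes, Polycomb-bound developmental transcription factors, imprinted genes, p53 targets, interferon response, cell cycle, cholesterol synthesis, amino acid and integrated stress response, glycolysis and hypoxia, FGF and MAPK feedback targets, Wnt targets and fibroblast markers. Some of them stand for other cell types. In the scrambled group of the Tet1 set, 7 of 21 fibroblast markers, 11 of 23 primitive endoderm genes and 11 of 22 trophectoderm genes lay above the median probe set. Of the 581 genes in the lists, 18 were in more than 1 list. Each list was tested with camera from limma, which asks whether its members shift relative to all other genes, with a preset inter-gene correlation of 0.01 and again with an estimated correlation, adjusted over the 24 lists within each of the 5 comparisons. The estimated setting also takes fewer degrees of freedom, so it can raise a p-value without a higher correlation. A call lost under it is therefore not credited to the correlation alone.

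The genes named in the text follow a rule. It uses only probe sets with exactly 1 symbol that is not a RIKEN or Gm name (18148 probe sets). It takes Tet1, Tet2, Tet3, Sin3a and Sin3b, then the 10 highest and 10 lowest of the calls for both Tet1 shRNAs and of the Sin3A calls. It adds the 4 highest and 4 lowest of the contrast between the Tet1 shRNAs, the 5 highest and 5 lowest shared by the Tet1 and Sin3A knockdowns, 4 with opposite signs, and the 3 highest and 3 lowest differences between the Tet1 and Sin3A effects. Up to 4 members of each gene list complete it. Groups, models, thresholds, gene lists and this rule were set before the data were examined, and genes named outside the rule are marked as such.

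The scripts were tested on simulated data drawn from the set means and the fitted spreads of these arrays, with changes of known size added to some probe sets. Of simulated changes of 0.5 on the log2 scale, 77.6% were recovered for Tet1 shRNA 4 against scrambled, 95.5% for Sin3A shRNA against scrambled and 68.7% for the difference between the Tet1 and Sin3A effects, each over the 67 probe sets changed by that size among 21212. The share of false calls was 9.93% (14 calls) for Tet1 shRNA 4, above the threshold of 5%, 4.61% for Sin3A shRNA and 3.42% for the difference. At 0.3 the shares were 13.4%, 22.4% and 4.48%, and at 1, over 66 probe sets, they were 100%, 100% and 97.0%. Alternatives covered the normalization, a filter on dim probe sets, a fold-change minimum, the variance model, the arrays in the fit, a replicate block, the list correlation and leaving out each array in turn. No sample was left out of the reported values. Arrays give no read depth, and their number limits the precision.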

Results

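Gene expression was measured on 15 Affymetrix arrays of E14TG2a.4 cells, a mouse embryonic stem cell line grown without feeder cells in the presence of leukaemia inhibitory factor. Lentiviruses had delivered a short hairpin RNA (shRNA), which directs the breakdown of a matching messenger RNA, and puromycin selection (2 µg per ml) had begun 36 hours later and lasted 72 hours. The Tet1 set held a scrambled hairpin, Tet1 shRNA 4 and Tet1 shRNA 5, and the Sin3A set held its own scrambled hairpin and a Sin3A shRNA, with 3 arrays in each of the 5 groups. Tet1 encodes a dioxygenase that oxidises methylated cytosine in DNA, and Sin3a encodes the scaffold of a histone deacetylase co-repressor complex. Replicate arrays of a group correlated across probe sets with r between 0.994 and 0.998. In the Tet1 set, replicate 2 of the scrambled group and replicate 2 of Tet1 shRNA 4 deviated from their groups in a similar way (r = 0.517 between their deviations across 21212 probe sets, which are not independent replicates), and the other pairs of arrays from different groups of that set lay between -0.455 and 0.281. The number of arrays limits the precision of all values below.

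The targeted transcripts were lower in every array of the matching knockdown. The Tet1 probe set had a log2 level of 12.20 ± 0.02 with the scrambled hairpin, 10.42 ± 0.03 with Tet1 shRNA 4 and 10.09 ± 0.14 with Tet1 shRNA 5 (SD, n = 3 each). These were 3.43-fold and 4.30-fold reductions, with log2 changes of -1.78 ± 0.07 and -2.10 ± 0.07 (SE, limma adjusted p = 2.1e-06 and 1.5e-06). The difference between the hairpins for Tet1 did not pass (-0.33 on the log2 scale, limma adjusted p = 0.17), although all 3 shRNA 5 arrays (9.94 to 10.20) lay below all 3 shRNA 4 arrays (10.39 to 10.44). The Sin3a probe set fell from 10.93 ± 0.06 to 9.38 ± 0.04 (SD, n = 3 each) with the Sin3A shRNA, a 2.93-fold reduction (log2 change -1.55 ± 0.05, SE, limma adjusted p = 1.3e-05).

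**Figure D1:**
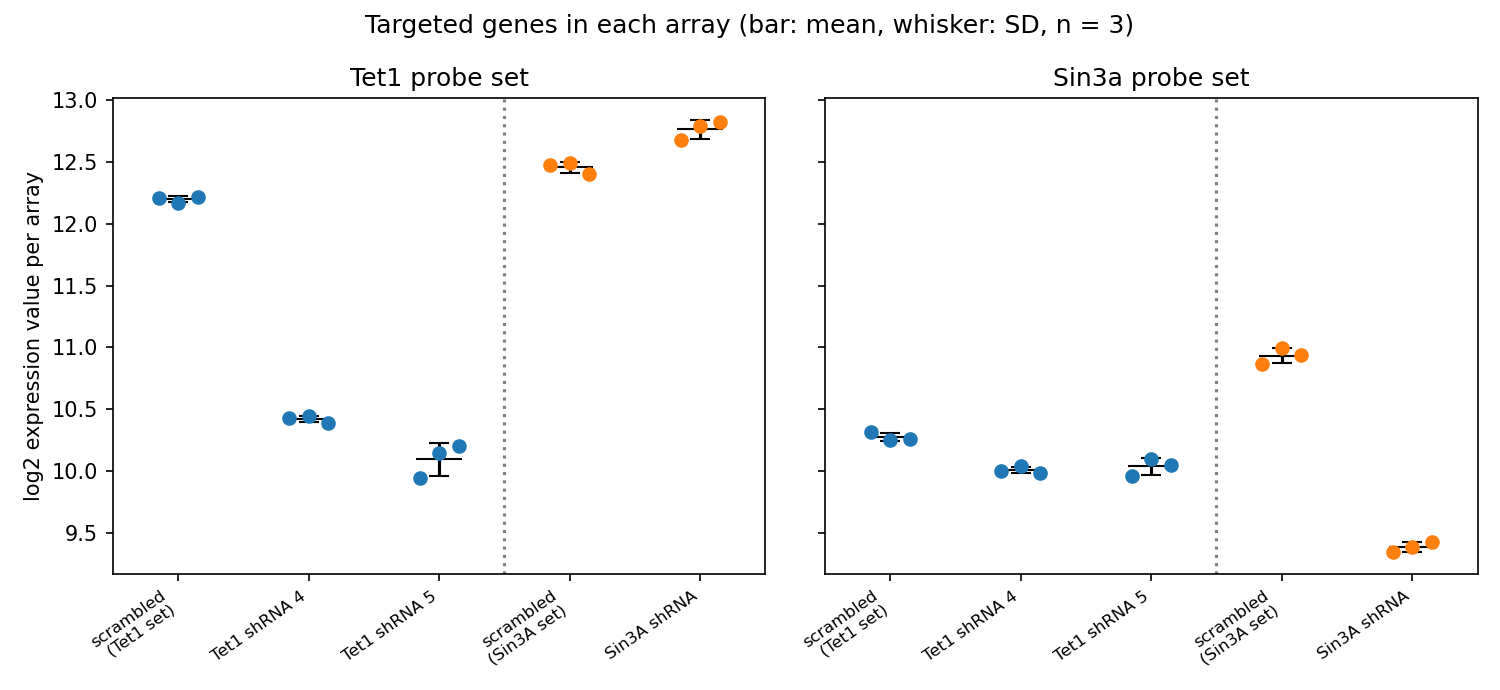
Log2 expression values of the Tet1 and Sin3a probe sets in each of the 15 arrays, with the mean (bar) and SD (whisker) of each group of 3. The 6 Tet1 shRNA arrays lie below the scrambled arrays of their set for Tet1, and the 3 Sin3A shRNA arrays lie below theirs for Sin3a. The dotted line parts both sets, which appear to have been normalized separately.

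Each targeted gene also moved, by less, in the other knockdown. Sin3a was lower with Tet1 shRNA 4 (-0.27 ± 0.06, SE, limma adjusted p = 0.015) and with Tet1 shRNA 5 (-0.24 ± 0.06, limma adjusted p = 0.022), and Tet1 was higher with the Sin3A shRNA (0.31 ± 0.06, limma adjusted p = 0.0068). The Sin3a call depended on single arrays. For shRNA 4 it was lost without scrambled replicate 1 (adjusted p = 0.0504) or without replicate 1 or 3 of that shRNA (0.0563 and 0.0539), and for shRNA 5 without scrambled replicate 1 or 3 (0.0669 and 0.0582) or replicate 1 or 3 of that shRNA (0.0868 and 0.0582). Sin3b, the paralogue of Sin3a, was lower with Tet1 shRNA 5 (-0.28 ± 0.06, limma adjusted p = 0.011; 0.0504 without replicate 2 of that shRNA), while with shRNA 4 its value of -0.16 did not pass (limma adjusted p = 0.12). Tet2 and Tet3, which encode the other enzymes of the Tet family, did not pass with either Tet1 shRNA (log2 changes 0.10 and -0.11 for Tet2, -0.09 and -0.06 for Tet3). In the Sin3A knockdown Tet2 was higher by 0.21 (limma adjusted p = 0.033), and this call was lost without scrambled replicate 2 or 3 or without any 1 of the 3 Sin3A shRNA arrays (adjusted p = 0.0548 to 0.117).

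The comparison of each Tet1 shRNA with the scrambled hairpin asks which transcripts change when Tet1 is depleted, and the changes common to both hairpins were taken as the Tet1 response. Among the genes that could be named, the largest common increases were in Gfra2, a receptor for ligands of the GDNF family (2.11 ± 0.11 with shRNA 4 and 2.22 ± 0.11 with shRNA 5, log2 change ± SE), in Hal, the enzyme that deaminates histidine (1.81 and 1.74), and in A2m, a protease inhibitor (1.97 and 1.55). Oas2, Scd1, Skida1, Tgfbi, Sema5b, Eomes and Nol4l followed, with changes of at least 1.24 for both. The largest common decreases besides Tet1 were in the actin-binding protein gene Cnn2 (-2.22 ± 0.07 and -1.92 ± 0.07), in Thbs1, which encodes a secreted matrix glycoprotein (-2.25 and -1.88), and in Fndc3c1 (-2.18 and -1.81). Pramel19, Klhl13, the imprinted gene Peg10, the translation factor gene Eif4g3, the ascorbate transporter gene Slc23a1 and the keratin gene Krt8 fell by 1.39 or more with both hairpins. All of these genes passed for both shRNAs (n = 3 arrays per group, limma adjusted p of 0.00063 or less).

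Tet1 shRNA 4 changed 2459 probe sets at an adjusted p under 0.05 (1460 higher, 999 lower), and Tet1 shRNA 5 changed 2934 (1775 higher, 1159 lower). Of these, 1146 were higher and 722 lower with both, against 122 and 54.6 for independent lists of these sizes, and 50 of the higher and 36 of the lower changed at least 2-fold with both. After repeated quantile normalization 1480 were higher and 1205 lower with shRNA 4, 1611 and 1397 with shRNA 5, and 1115 and 893 with both. The excess of higher over lower calls thus depends in part on the scaling. The log2 changes of both shRNAs correlated with r = 0.858 (Spearman rho 0.775) across probe sets, which are not independent replicates. Both comparisons share the 3 scrambled arrays, and simulated unchanged groups gave r = 0.5, a same-sign share of 66.6% (observed 78.2%), a covariance of 0.00517 (observed 0.0477) and 0 shared calls. The simulated groups held no changes, so hardly any calls could arise there and the 0 shared calls tell little. The 3 scrambled arrays were not divided between the comparisons, so part of the excess of shared calls over independent lists may come from the shared controls. The observed covariance exceeded the simulated one by 0.0425.

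**Figure D2:**
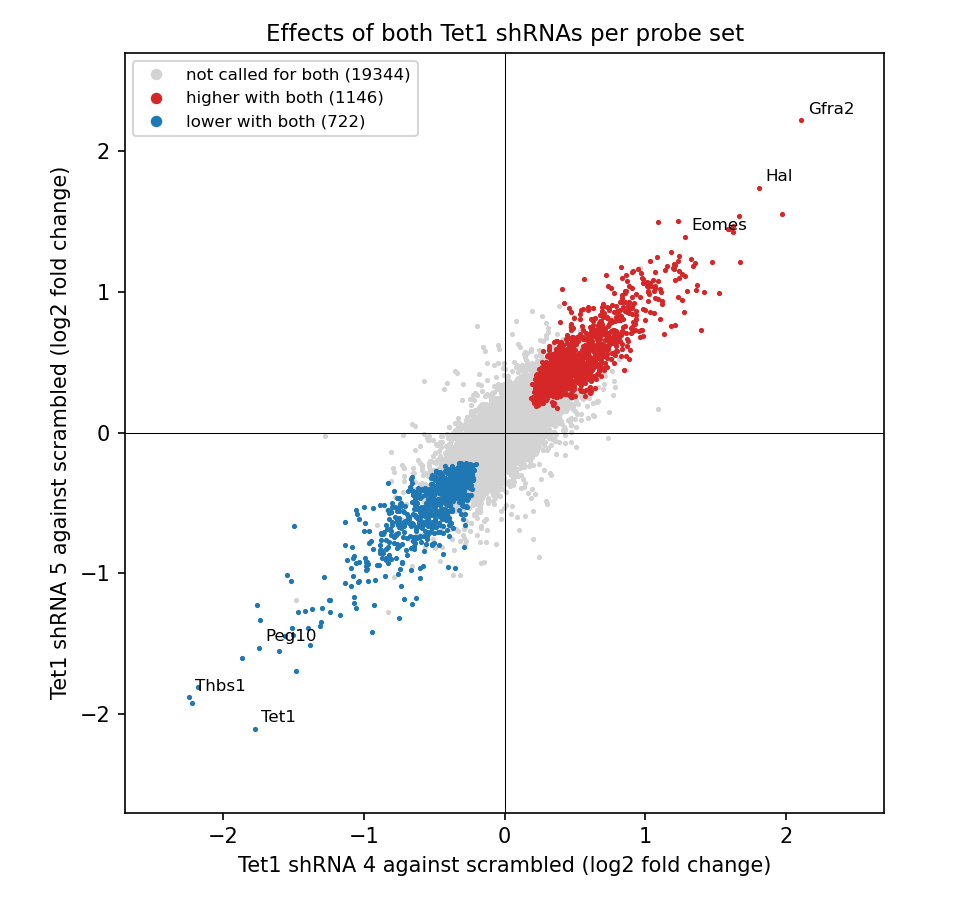
Log2 change against scrambled with Tet1 shRNA 4 (x axis) and Tet1 shRNA 5 (y axis), 1 point per probe set. Red points are the 1146 probe sets higher and blue points the 722 lower with both (limma adjusted p under 0.05), and named genes such as Gfra2 (2.11 and 2.22) and Thbs1 (-2.25 and -1.88) lie near the diagonal.

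Imprinted genes are expressed from 1 parental copy. Of 31 measured members, 10 fell with both shRNAs, 0 rose and 21 did not pass for both (12 fell and 1 rose when adjusted over the list alone). Peg10 fell by 1.74 and 1.53, Peg3 by 1.51 and 1.39, the growth factor gene Igf2 by 1.39 and 1.51 and Sgce by 1.08 and 0.81. The list shifted down with shRNA 4 (camera adjusted p = 1.6e-07, mean log2 change -0.36) and with shRNA 5 (3.57e-05, mean -0.31). Neither call held with an estimated correlation (adjusted p = 0.0675 and 0.201).

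The list of 2-cell-like genes, expressed in 2-cell embryos and a minor fraction of stem cells, shifted down by the same test. Of its 28 symbols 15 were matched, to 13 genes that are mostly Usp17-like and Tdpoz genes, so the list stands for a part of that programme. Whether probe sets of such related genes measure them separately was not tested, so its members may not be independent, here and below. Of the 13 genes, 5 fell with both shRNAs, 0 rose and 8 did not pass for both (5 and 0 when adjusted over the list alone). Tmem92 fell by 0.97 and 1.05, Zfp352 by 0.77 and 0.72 and the deubiquitinase gene Usp17lc by 0.62 and 0.41. The camera adjusted p was 9.72e-07 for shRNA 4 and 7.83e-05 for shRNA 5, and both calls were lost with an estimated correlation (adjusted p = 0.104 and 0.201).

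Genes of cholesterol synthesis shifted up with both shRNAs (camera adjusted p = 0.00328 and 0.0109, lost with an estimated correlation at adjusted p = 0.561 and 0.577). Of 18 members, 3 rose with both, 0 fell and 15 did not pass for both (3 and 0 when adjusted over the list alone). These were the enzyme genes Sc5d (0.57 and 0.47), Sqle (0.47 and 0.56) and Msmo1 (0.40 and 0.34).

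Other list shifts passed for 1 Tet1 shRNA. With shRNA 4, targets of the tumour suppressor p53 shifted down (camera adjusted p = 1.09e-06), the only list call of that comparison that held with an estimated correlation (adjusted p = 0.0254). The estimate for this list was -0.0285, below the preset value, so the call was not put to a higher correlation. With shRNA 4, 13 of its 26 members fell and 2 rose (16 and 2 when adjusted over the list alone), and with shRNA 5, 6 fell and 2 rose (11 and 2), where the camera adjusted p of 0.0562 did not pass. It passed for shRNA 5 without scrambled replicate 2 (0.0337) and without replicate 2 of shRNA 5 (0.0445). Trp53inp1 fell by 0.47 and 0.37 and Eda2r by 0.47 and 0.35, while Sesn1, a stress-induced regulator of growth signalling, rose by 1.08 and 1.25. Formative and early epiblast genes shifted down with shRNA 4 (camera adjusted p = 0.000695, 0.233 with an estimated correlation), where 9 of 15 fell and 2 rose (9 and 3 when adjusted over the list alone). With shRNA 5, 5 fell and 3 rose (6 and 4), and the list did not pass (adjusted p = 0.333). Among them Dnmt3b, a de novo DNA methyltransferase gene, fell by 0.99 and 0.64, Pim2 by 0.997 and 0.52 and Fgf5 by 0.66 and 0.36, and Lef1, a transcription factor gene of the Wnt pathway, rose by 0.91 and 1.15. The amino acid and integrated stress response list shifted down with shRNA 5 (camera adjusted p = 6.75e-05, 0.201 with an estimated correlation), where 12 of 26 fell and 3 rose (15 and 3 when adjusted over the list alone). With shRNA 4, 3 fell and 3 rose (5 and 3), and the adjusted p was 0.353. Without scrambled replicate 2, 9 lists passed for shRNA 5, against 4 with all arrays. When the arrays were split in other ways, as many lists passed in 4 of 10 splits for shRNA 4 and 5 of 10 for shRNA 5, the real one included. Chance is therefore not excluded for these list counts.

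The remaining lists did not pass for either shRNA with all arrays, and their members went both ways or mostly did not pass. Among 22 trophectoderm and placenta genes, 6 rose and 7 fell with both shRNAs (7 and 7 when adjusted over the list alone). Eomes, a T-box factor of trophoblast and mesendoderm, rose by 1.28 and 1.40, while the simple-epithelium keratins Krt8 (-1.40 and -1.39), Krt18 (-1.03 and -0.92) and Krt19 (-0.94 and -0.83) fell. Of 25 naive pluripotency genes 5 rose and 3 fell (7 and 3), with Tbx3 at 0.98 and 0.69 and Dppa3, a maternal-effect gene, at -0.99 and -0.97, where the Dppa3 call for shRNA 4 was lost without both arrays that stood apart (adjusted p = 0.0577). Of 23 primitive endoderm genes 3 rose, among them Sox7 (0.80 and 0.83), and 2 fell, Apoe (-0.72 and -1.18) and Lamb1 (-0.71 and -0.52) (3 and 3 when adjusted over the list alone). Of 20 mesendoderm and primitive streak genes 2 rose, Eomes and Bmp4 (0.44 and 0.50), and 0 fell (2 and 0). Of 18 neuroectoderm genes Pax6 (-0.64 and -0.49) and Nes (-0.75 and -0.47) fell and 0 rose (0 rose and 2 fell). Of 15 Nodal signalling genes 3 rose and 1 fell (4 and 1), among them Pmepa1 (0.78 and 0.56), Smad7 (0.61 and 0.37) and Skil (-0.76 and -0.54).

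Among 31 germline genes 2 rose, Dazl (0.74 and 0.77) and Stra8 (0.49 and 0.54), and 2 fell, among them the synaptonemal complex gene Sycp3 (-1.31 and -1.37) (3 and 2 when adjusted over the list alone). Of 62 developmental transcription factor genes bound by Polycomb, 6 rose and 1 fell (6 and 1), with Pax8 at 0.94 and 0.99, Tbx15 at 0.66 and 0.72, Wt1 at 0.42 and 0.92 and the neurogenic factor gene Neurod1 at -1.76 and -1.23. Of 38 Hox genes 1 rose, Hoxc12 (0.80 and 0.61), and 0 fell (1 and 0). Of 28 Polycomb components Cbx2 rose (0.39 and 0.49) and 1 fell (1 and 0). Of 22 SIN3 complex genes 1 fell, Sin3a, and 0 rose (1 and 0). Of 23 genes of the DNA methylation machinery 1 rose, Mbd2 (0.44 and 0.52), and 2 fell, Tet1 and Dnmt3b (1 and 3). Of 27 interferon response genes 2 rose, Oas2 (1.67 and 1.54) and Xaf1 (1.13 and 0.70), and 3 fell, among them Gbp2 (-1.42 and -1.27) (2 and 4). Of 35 cell cycle genes Ccnd2, which encodes cyclin D2 (0.73 and 1.05), and E2f1 (0.30 and 0.39) rose and 0 fell (2 and 0), and the E2f1 call for shRNA 4 was lost without both arrays that stood apart (adjusted p = 0.0591). Of 25 glycolysis and hypoxia genes 4 rose and 0 fell (5 and 2), among them Hk1 (0.68 and 0.48) and Ndrg1 (0.37 and 0.38). Of 20 FGF and MAPK feedback targets 4 rose and 2 fell (5 and 2), with Etv4 at 0.66 and 0.76 and Dusp4 at -0.65 and -0.65. Of 16 Wnt targets 4 rose and 0 fell (5 and 0), among them Lef1 and Notum (0.82 and 0.65). Of 21 fibroblast markers Thy1 (0.82 and 0.81) and Vim (0.70 and 0.83) rose, and Acta2 (-1.30 and -1.25) and Tagln (-1.06 and -0.92), both genes of the actin cytoskeleton, fell (2 and 2). With shRNA 4 the mean, median and test differed in sign for trophectoderm, mesendoderm, DNA methylation machinery, Polycomb components, Hox genes and interferon response, and with shRNA 5 for trophectoderm, mesendoderm, neuroectoderm and DNA methylation machinery.

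**Figure D3:**
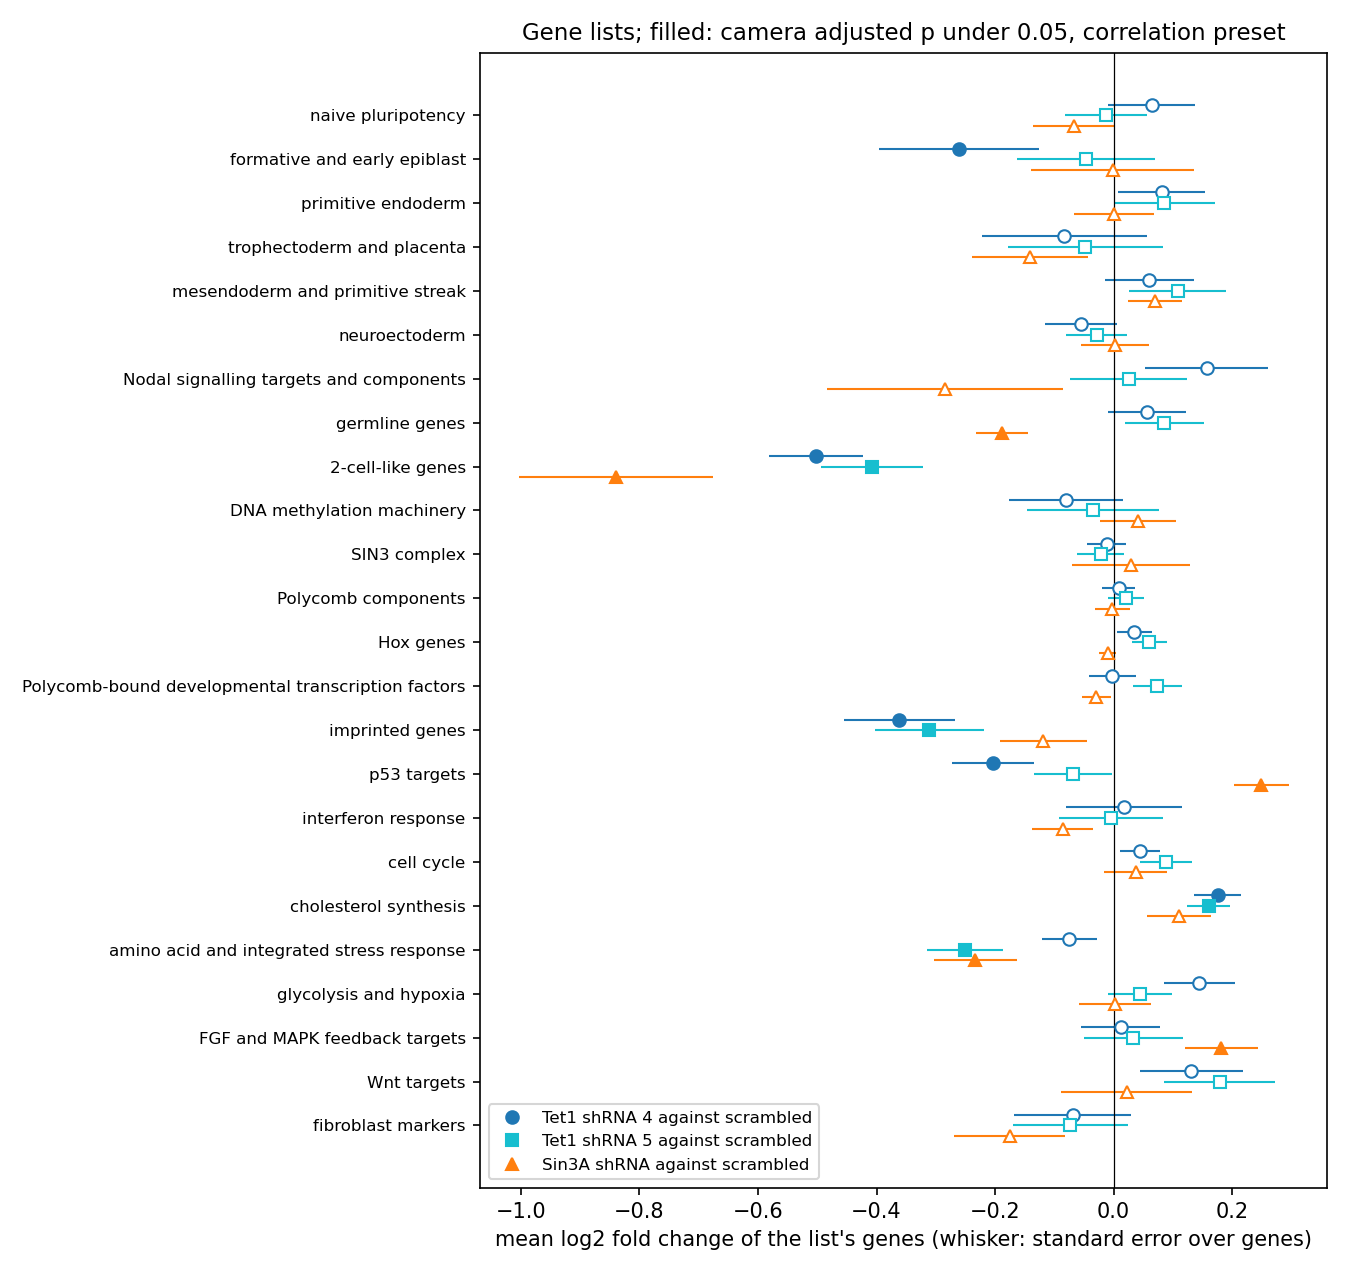
Mean log2 change of each of the 24 gene lists (x axis) for Tet1 shRNA 4, Tet1 shRNA 5 and Sin3A shRNA, each against its own scrambled group. Whiskers are standard errors over the genes of a list, and filled symbols passed camera with a preset correlation (5, 4 and 5 lists). The 2-cell-like list is lowest in all 3 comparisons, and the p53 list lies on opposite sides of 0 for the Tet1 shRNAs and the Sin3A shRNA. With Tet1 shRNA 5 the p53 list did not pass (mean -0.068).

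The contrast between the Tet1 hairpins asks where they differ. Compared with shRNA 4, shRNA 5 gave higher values of the homeobox gene Nkx2-9 (0.79 ± 0.10, log2 difference ± SE), Vrtn (0.72 ± 0.06), Foxi3 (0.72 ± 0.08) and Ccno (0.68 ± 0.08). Lower values were measured for the stress-response genes Nupr1 (-0.79 ± 0.10) and Chac1 (-0.61 ± 0.08), the glycine transporter gene Slc6a9 (-0.75 ± 0.10) and Pck2 (-0.65 ± 0.09), with limma adjusted p between 0.014 and 0.038 for these 8 genes. None of the 8 calls held when arrays were left out in turn: all 8 were lost without replicate 1 of shRNA 4 (adjusted p = 0.125 to 0.215), without replicate 1 of shRNA 5 (0.134 to 0.168) and without replicate 3 of shRNA 5 (0.065 to 0.169). Without replicate 2 of shRNA 5 the calls of all but Vrtn were lost (0.169 to 0.219), without replicate 3 of shRNA 4 those of all but Vrtn and Chac1 (0.0666 to 0.0961), and without replicate 2 of shRNA 4 those of Ccno, Nupr1, Slc6a9, Pck2 and Chac1 (0.0729 to 0.131). In total 30 probe sets passed, 12 higher and 18 lower with shRNA 5 (1836 at an unadjusted p under 0.05). The share of higher calls was 40% as deposited, 51.6% after centring each array on its median and 33.3% after repeated quantile normalization. This count rested on each of the 6 shRNA arrays, while scrambled arrays were not left out singly for it. It was 0 without replicate 1 of shRNA 4, or without replicate 1 or 3 of shRNA 5, 1 without replicate 2 of shRNA 5, and 4 and 6 without replicates 2 and 3 of shRNA 4. With all arrays it was also 0 with a replicate block or with only the 2 groups compared in the fit.

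By list, p53 targets were higher with shRNA 5 than with shRNA 4 (camera adjusted p = 6.49e-07, mean difference 0.14), which held with an estimated correlation (adjusted p = 0.0232, where the estimate of -0.0285 lay below the preset 0.01). Of the 26 members 0 passed singly (7 higher and 0 lower when adjusted over the list alone). Formative and early epiblast genes were also higher as a list (adjusted p = 2.65e-09), with 0 of 15 passing singly (9 higher and 0 lower when adjusted over the list alone). Amino acid and integrated stress response genes were lower as a list (3.77e-08), with 3 of 26 lower and 0 higher (9 and 2 when adjusted over the list alone). Both missed the threshold with an estimated correlation (adjusted p = 0.0534 for each). Naive pluripotency (0.00397), glycolysis and hypoxia (0.00129) and Nodal signalling (0.0136) passed as lower, and cell cycle (0.0124), developmental transcription factors bound by Polycomb (0.0124) and 2-cell-like genes (0.0324) as higher, with adjusted p from 0.167 to 0.65 under an estimated correlation. Of their members 1 passed singly, a Polycomb-bound gene that was higher. Adjusted over the list alone, 2 were higher and 6 lower for naive pluripotency, 0 and 2 for glycolysis, 0 and 4 for Nodal, 4 and 2 for cell cycle, 6 and 0 for the Polycomb-bound list and 3 and 0 for 2-cell-like genes. Leaving out single arrays of the shRNAs ended the last 3 of these calls and the Nodal call. Without replicate 1 of shRNA 4 the Nodal list gave 0.0653 and the Polycomb-bound list 0.108, and the latter gave 0.138 without replicate 3 of shRNA 4 and 0.113 without replicate 1 of shRNA 5. Cell cycle gave 0.100 and 0.134 without replicate 2 of shRNA 4 and of shRNA 5. The 2-cell-like list gave 0.174 without replicate 2 of shRNA 4, and 0.218 and 0.114 without replicates 2 and 3 of shRNA 5. The mean, median and test differed in sign for fibroblast markers.

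The Sin3A knockdown was compared with its own scrambled group to ask which transcripts change when this co-repressor is depleted. A single Sin3A hairpin was used, so its off-target effects cannot be told apart from those of Sin3a loss, here and in the overlap with the Tet1 response. Among the genes that could be named, the largest decreases were in Lefty1 (-2.31 ± 0.07, log2 change ± SE, 4.97-fold) and Lefty2 (-1.86 ± 0.08, 3.64-fold), which encode secreted inhibitors of Nodal signalling. Pramel19 (-1.79), the actin-binding protein gene Tagln (-1.76), the deubiquitinase gene Usp17la (-1.75), Pmp22 (-1.54), Thbs1 (-1.44), the prostaglandin synthase gene Ptgs2 (-1.43) and the metallothionein gene Mt1 (-1.42) fell as well. The largest increases were in the sodium channel subunit gene Scn3b (1.78 ± 0.05, 3.43-fold) and in Gfra2 (1.70 ± 0.07, 3.25-fold). Spink10 (1.54), the deubiquitinase gene Stambpl1 (1.53), Lactb (1.5), Soga3 (1.40), Ccdc141 (1.39), Lef1 (1.35), Khdc3 (1.33) and Hivep2 (1.32) followed. All of these genes had a limma adjusted p of 0.00042 or less (n = 3 arrays per group).

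At the same threshold the Sin3A shRNA changed 5261 probe sets, 2592 higher and 2669 lower, of which 50 and 72 changed at least 2-fold. Without Sin3A shRNA replicate 2 the count was 3359.

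Of 26 targets of p53 measured in the Sin3A knockdown, 18 rose, 0 fell and 8 did not pass (18 and 0 when adjusted over the list alone), with Perp at 0.83, Sesn1 at 0.76, Ddit4l at 0.58 and Plk2 at 0.53. The camera adjusted p was 4.82e-06, and 0.22 with an estimated correlation. FGF and MAPK feedback targets shifted up (camera adjusted p = 0.00969, also 0.22 with an estimated correlation). The estimate for this list was 0.00997, about the preset 0.01, so a higher correlation did not end this call. Of 20 members 6 rose and 1 fell (8 and 2 when adjusted over the list alone), among them Spred1, an inhibitor of Ras signalling, at 0.73, Etv1 at 0.55 and Fosl1 at 0.47.

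Of the 13 measured 2-cell-like genes, 9 fell and 0 rose (10 and 0 when adjusted over the list alone), with Usp17la at -1.75, Usp17lb at -1.39, the arginase gene Arg2 at -1.36 and Zfp352 at -1.30 (camera adjusted p = 1.45e-07, 0.22 with an estimated correlation). Genes of the amino acid and integrated stress response shifted down, with 12 of 26 lower and 0 higher (13 and 1 when adjusted over the list alone). Chac1 fell by 1.30, Nupr1 by 1, Atf4, the central transcription factor of this response, by 0.68 and Pck2 by 0.67 (camera adjusted p = 0.00119, 0.22 with an estimated correlation). Germline genes shifted down as well, with 13 of 31 lower and 3 higher (15 and 3 when adjusted over the list alone), among them Tex11 at -0.61 and Rnf17 at -0.46 (camera adjusted p = 0.00508, 0.47 with an estimated correlation). No list call of this comparison held with an estimated correlation.

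The Nodal signalling list had 2 members that rose and 5 that fell (2 and 5 when adjusted over the list alone), and it did not pass (camera adjusted p = 0.194) although Lefty1 and Lefty2 had the lowest values of all genes that could be named, while Smad3 rose by 0.48. In naive pluripotency 3 of 25 rose and 5 fell (4 and 7), with Pecam1 at -0.92, Dppa3 at -0.91, Klf2 at -0.65 and Gbx2 at 0.65. In the epiblast list 3 of 15 rose and 5 fell (4 and 5), with Otx2, a homeobox factor of the early epiblast, at -1.09, Sox11 at 0.57 and Lef1 at 1.35. In primitive endoderm 3 of 23 rose and 3 fell (3 and 3), with Lama1 at 0.81 and Dab2 at -0.86. In trophectoderm and placenta 4 of 22 rose and 9 fell (4 and 11), with Plet1 at 1, Krt8 at -1.01, Krt18 at -0.70 and Tfap2c at -0.62 (list adjusted p = 0.0839). In mesendoderm 5 of 20 rose and 2 fell (5 and 2), with Bmp4 at 0.45 and Kdr at 0.38. In neuroectoderm 1 of 18 rose, Ncam1 at 0.77, and 2 fell (1 and 2), with Nes at -0.36. In imprinted genes 2 of 31 rose and 6 fell (2 and 6), with Igf2 at -1.26, Phlda2 at -1.25, Impact at -0.62 and Peg3 at 0.93.

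Of 23 genes of the DNA methylation machinery 6 rose and 4 fell (7 and 5), with Idh2 at 0.63, Gadd45b at -0.73 and Uhrf2 at -0.47. Of 22 SIN3 complex genes 9 rose and 4 fell (11 and 6), with Ing2 at 0.87, Ing1 at 0.56, Phf12 at -0.41 and Sin3a itself at -1.55. Of 28 Polycomb components 2 rose and 3 fell (2 and 3), with Phc3 at 0.47 and Pcgf1 at -0.34, and of 38 Hox genes 0 rose and 1 fell (0 and 0). Of 62 developmental transcription factor genes bound by Polycomb 1 rose, Neurod1 at 0.77, and 9 fell (1 and 9), with Sox21 at -0.43, Tbx4 at -0.42 and Gata3 at -0.42. In the interferon response 2 of 27 rose and 8 fell (2 and 8), with Eif2ak2 at 0.66, Gbp2 at -0.58 and Irf9 at -0.57. In the cell cycle list 7 of 35 rose and 4 fell (8 and 4), with Ccnd3 at 0.67, Rbl2 at 0.57 and Ccnd2 at -1.16. In cholesterol synthesis 5 of 18 rose and 2 fell (9 and 3), with Msmo1 at 0.42 and Dhcr7 at -0.37 (list adjusted p = 0.0839; 0.0392 without Sin3A shRNA replicate 1). In glycolysis and hypoxia 4 of 25 rose and 6 fell (7 and 7), with Pdk1 at 0.58 and Slc16a3 at -0.54. In Wnt targets 4 of 16 rose and 3 fell (4 and 4), with Lef1 at 1.35 and Notum at -0.68. In fibroblast markers 2 of 21 rose and 6 fell (3 and 6), with Tagln at -1.76, Pdgfrb at -0.58 and Acta2 at -0.54 (list adjusted p = 0.0839; 0.0299 without scrambled replicate 2 and 0.0324 without Sin3A shRNA replicate 1). The mean, median and test differed in sign for the epiblast, neuroectoderm, Polycomb components, Polycomb-bound, glycolysis and Wnt lists.

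The overlap of the Tet1 and Sin3A responses asks how far the changes were shared. Gfra2, the growth factor gene Fgf10 (1.20 and 1.17 with the Tet1 shRNAs, 1.12 with the Sin3A shRNA), the arginine methyltransferase gene Prmt8 (0.97, 1.13 and 1.13), Hal (1.81, 1.74 and 0.96) and Nol4l (1.24, 1.25 and 0.95) were the highest of the genes that rose in all 3 knockdown groups. Pramel19 (-1.87, -1.60 and -1.79), Thbs1 (-2.25, -1.88 and -1.44), Igf2 (-1.39, -1.51 and -1.26), Eif4g3 (-1.48, -1.69 and -1.03) and Krt8 (-1.40, -1.39 and -1.01) were the lowest of those that fell in all 3. Other genes moved in opposite directions. Acsf2, an acyl-CoA synthetase gene (1.53, 0.99 and -1.02), and the bicarbonate transporter gene Slc4a5 (0.90, 0.90 and -0.97) rose with the Tet1 shRNAs and fell with the Sin3A shRNA, and Peg3 (-1.51, -1.39 and 0.93) and Neurod1 (-1.76, -1.23 and 0.77) did the reverse.

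Of the 961 probe sets called in both knockdowns, 642 (66.8%) moved in the same direction and 319 in opposite directions. Higher in both were 358 probe sets, against 140 for independent lists (odds ratio 3.63, Fisher's exact test p = 1.9e-69), and lower in both were 284, against 90.8 (odds ratio 4.92, Fisher's exact test p = 6.9e-77). Of the opposite calls, 212 were higher with the Tet1 shRNAs and lower with the Sin3A shRNA, against 144 (odds ratio 1.63, Fisher's exact test p = 3.9e-09), and 107 were the reverse, against 88.2 (odds ratio 1.26, Fisher's exact test p = 0.032). These odds ratios take no account of signal level, which raised the counts expected. When the Sin3A calls were shuffled 1000 times among probe sets of like level, the mean was 208 for higher in both (highest 242) and 124 for lower in both (highest 151), below the observed 358 and 284. For the opposite calls the means were 204 (160 to 241 in the shuffles) and 124 (95 to 167), so the 212 and 107 observed lay within the shuffles. The 2 sets share no arrays. Across all probe sets the mean Tet1 change and the Sin3A change correlated weakly (r = 0.184, Spearman rho 0.101), and probe sets are not independent replicates.

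**Figure D4:**
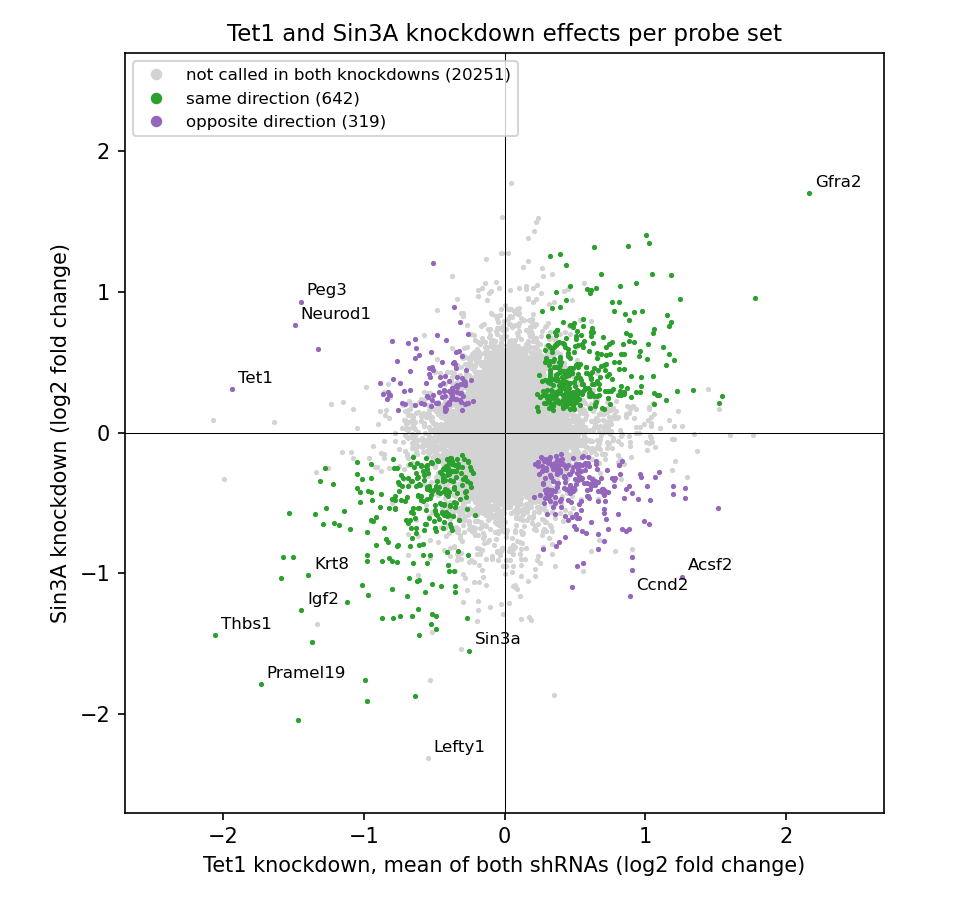
Mean log2 change of both Tet1 shRNAs (x axis) and log2 change of the Sin3A shRNA (y axis), each against its own scrambled group, 1 point per probe set. Green points are the 642 probe sets called in both knockdowns in the same direction and purple points the 319 called in opposite directions. Gfra2 and Thbs1 lie at the ends of the shared changes, and Peg3 and Acsf2 among the opposite ones.

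The difference between the effects was tested directly, as the mean Tet1 effect minus the Sin3A effect. It was highest for Acsf2 (2.28 ± 0.17, log2 difference ± SE), Lefty2 (2.22 ± 0.23) and Ccnd2 (2.05 ± 0.10), and lowest for Peg3 (-2.38 ± 0.10), Neurod1 (-2.26 ± 0.13) and Tet1 itself (-2.25 ± 0.09), all with a limma adjusted p of 1.3e-05 or less. In all, 4241 probe sets passed for this difference, 2393 higher and 1848 lower (2302 and 2131 after repeated quantile normalization). Each knockdown was measured in its own array set, and the sets appear to have been normalized separately. A different scale of log2 changes in the sets therefore cannot be told apart from a difference between the knockdowns.

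Targets of p53 differed most clearly among the lists. Higher and lower here refer to the signed difference, not to the size of an effect. Of 26 members, 16 had a lower and 1 a higher effect in the Tet1 knockdowns than in the Sin3A knockdown (18 and 1 when adjusted over the list alone; mean difference -0.38, camera adjusted p = 1.31e-08). This was the only list call of the comparison that held with an estimated correlation (adjusted p = 0.000959). The estimate for this list was -0.0039, below the preset 0.01, so the call was not put to a higher correlation. The mean change of the p53 list was -0.20 with shRNA 4, -0.068 with shRNA 5 and 0.25 with the Sin3A shRNA. The shift with shRNA 5 did not pass (camera adjusted p = 0.0562), and the Tet1 shRNAs differed for this list (6.49e-07). The averaged Tet1 effect thus does not describe both hairpins equally. The signed difference was higher for germline genes (9 of 31 higher, 2 lower, camera adjusted p = 0.00387, or 12 and 2 when adjusted over the list alone), 2-cell-like genes (6 of 13 higher, 0 lower, 0.0101, or 6 and 0) and Nodal signalling (7 of 15 higher, 2 lower, 0.0345, or 7 and 2). It was lower for imprinted genes (8 of 31 lower, 3 higher, 0.0412, or 9 and 3). The 2-cell-like list fell less with the Tet1 shRNAs (mean -0.50 and -0.41) than with the Sin3A shRNA (-0.84). Imprinted genes fell more with the Tet1 shRNAs (mean -0.36 and -0.31) than with the Sin3A shRNA (-0.12). With an estimated correlation each of these 4 lists had an adjusted p of 0.422. The Nodal and imprinted calls were lost without scrambled replicate 2 of the Tet1 set (0.0507 for both) and without Sin3A shRNA replicate 1 (0.0551 and 0.0706), and the imprinted call also without Tet1 shRNA 5 replicate 1 (0.0506) or Sin3A shRNA replicate 3 (0.0676). The mean, median and test differed in sign for the naive, mesendoderm, Polycomb components, cholesterol and fibroblast lists.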

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

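The tests of a deeper knockdown and of an off-target effect below were chosen only after the differences between the Tet1 shRNAs had been seen. The effects of both Tet1 shRNAs against the same scrambled arrays were compared by a direct test of their difference, and 30 probe sets differed. Those of the 8 genes named by rule were Nkx2-9 (0.79), Vrtn (0.72), Foxi3 (0.72), Ccno (0.68), Nupr1 (-0.79), Slc6a9 (-0.75), Pck2 (-0.65) and Chac1 (-0.61), as shRNA 5 minus shRNA 4 on the log2 scale. Mean differences of 9 gene lists passed camera with a preset correlation. They were 0.21 for formative and early epiblast, 0.14 for p53 targets, 0.0948 for 2-cell-like genes, 0.0759 for developmental transcription factors bound by Polycomb and 0.0428 for cell cycle. They were -0.18 for the amino acid and integrated stress response, -0.13 for Nodal signalling, -0.10 for glycolysis and hypoxia and -0.0775 for naive pluripotency. Only the p53 list held with an estimated correlation, and its estimate of -0.0285 lay below the preset value.

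A deeper Tet1 knockdown with shRNA 5 would move a probe set further in the direction that both shRNAs share. Of the 30 probe sets, 2 were called in opposite directions by the shRNAs, and 9 others were called with shRNA 4 and differed against its direction. These 9 differed by at least 6.80 standard errors, but all 30 were picked for passing this difference, so that distance is no further evidence. The shRNA 4 arrays also enter both values, which favours differences against their direction. The directions argue against a deeper knockdown for these 11 only as far as their calls hold. Of the 19 left, 10 had the same sign with both shRNAs (52.6%, exact 95% interval 28.9% to 75.6%), which leaves it open for them. Probe sets are not independent of each other, so this interval is only descriptive. An off-target effect of 1 hairpin may explain probe sets called with 1 shRNA only, and 19 of the 30 were so called (14 with shRNA 5, 5 with shRNA 4). With 2 hairpins and no rescue the off-target effect and the deeper knockdown cannot be told apart for the 14 called with shRNA 5 alone. The 10 splits of the 6 shRNA arrays are too few for a share under 0.05: the real split (1 of the 10) gave 30 probe sets and the highest other 0, and for the lists it (1 of the 10) gave 9 and the highest other 7.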

How the results depend on the processing

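The choice of both arrays that stand apart, and of probe sets without ties, was made after the data had been seen. No called value of a named gene or gene list changed its sign. The direction with more calls did change for some counts: the overlap had 39 higher and 48 lower with the 1.5-fold minimum (358 and 284 without it), the calls between the Tet1 shRNAs had 16 and 15 after median centring (12 and 18 as deposited), and the nearly even Sin3A split went from 2592 and 2669 to 2483 and 2461 without Sin3A shRNA replicate 1 and 2159 and 2151 without scrambled replicate 2. With a change of at least 1.5-fold required as well, 656 probe sets passed for Tet1 shRNA 4, 657 for Tet1 shRNA 5, 463 for both, 12 between the shRNAs, 667 for Sin3A, 87 in the overlap and 1185 for the difference between the effects, as the added minimum removes smaller changes by construction. The count between the Tet1 shRNAs moved most: it was 62 without the lowest 30% of probe sets, 48 with a trended robust variance, 188 with all 15 arrays in 1 fit, 0 with only the 2 groups compared, 1 without both arrays that stand apart and 0 to 6 without 1 replicate each (0 without Tet1 shRNA 4 replicate 1, 6 without its replicate 3). The cause was not tested. Without 1 replicate each the Sin3A count was 3359 (Sin3A shRNA replicate 2) to 4944 (Sin3A shRNA replicate 1).

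With an estimated correlation, 1 list passed for Tet1 shRNA 4, 0 for Tet1 shRNA 5, 1 between them, 0 for Sin3A and 1 for the difference between the effects. For Tet1 shRNA 5, 8 lists passed without both arrays that stand apart, and 4 to 9 without 1 replicate each (9 without scrambled replicate 2). For the difference, 3 lists passed without both arrays that stand apart and 3 to 6 without 1 replicate each (3 without scrambled replicate 2 of the Tet1 set or without Sin3A shRNA replicate 1). The cause was not tested. Probe sets near background limit what dim genes can show.

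Replicates were also fitted as a replicate block, although the labels do not say that numbers pair the arrays and not every sample correlates best with its own number (deviations of scrambled and Tet1 shRNA 4 arrays of the same number had r from 0.171 to 0.517). With the replicate block 0 probe sets passed between the Tet1 shRNAs, the Id genes among those lost, and 3 lists for the difference between the effects, where Nodal signalling (adjusted p = 0.0537) and imprinted genes (0.0555) were lost. The other counts stayed within 1.5 times those reported, and 17 calls of named genes were lost. When each array was left out in turn, 1834 values of named genes kept their side of the threshold, 151 lost it and 1 gained it.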

Other observations

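The families in the next 2 paragraphs and the tests of a batch by replicate number, of the lower Sin3a level and of the control hairpin were chosen only after values had been seen. Fatty acid desaturases and elongases shape the length and saturation of membrane lipids. Of 15 members, 6 were higher with both shRNAs and 0 lower (5 and 0 after either other scaling). These were Scd1 (1.62 and 1.47), Scd2 (0.61 and 0.49), Elovl5 (0.69 and 0.70), Fads1 (0.65 and 0.49), Fads2 (0.52 and 0.45) and Elovl2 (0.42 and 0.47). Elovl3 was lower with shRNA 5 (-0.26, limma adjusted p = 0.0241) and had a value of -0.01 with shRNA 4. With the Sin3A shRNA 5 were higher and 3 lower, and no test of the family as a whole was run. Of 66 mitochondrial complex I, complex IV and ATP synthase subunits 9 were higher and 0 lower with both Tet1 shRNAs (7 and 0 after either other scaling). These calls were 13.6% of the family (10.6% after either other scaling), against 8.81% of all probe sets. With the Sin3A shRNA 5 were higher and 5 lower, 15.2% of the family against 24.8% of all.

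All 5 Usp17-like deubiquitinase genes fell with the Sin3A shRNA (mean -1.22), under each scaling, and 2 of them fell with both Tet1 shRNAs. Whether their probe sets measure these related genes separately was not tested, so the 5 may not be independent. The Id genes, inhibitors of basic helix-loop-helix factors, were higher with Tet1 shRNA 5 than with shRNA 4 for Id1 (0.55), Id2 (0.51) and Id3 (0.50), with limma adjusted p of 0.0277, 0.0277 and 0.0447, and Id4 had a value of -0.03. All 3 Id calls were lost without any 1 of the 6 Tet1 shRNA arrays (adjusted p = 0.0673 to 0.254, the lowest without Tet1 shRNA 5 replicate 3 and the highest without its replicate 2). Of 1061 olfactory receptor probe sets, mostly silent outside the nose, 0.189% were called with both Tet1 shRNAs (8.81% of all probe sets) and 3.30% with the Sin3A shRNA (24.8% of all).

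Scrambled replicate 2 and Tet1 shRNA 4 replicate 2 deviated from their groups together (r = 0.517 across probe sets). With the trend over signal level removed r was 0.471, which argues against a level-dependent distortion as the whole source. Scrambled replicate 2 and Tet1 shRNA 5 replicate 2 had r = -0.287, which argues against a batch that holds all arrays numbered 2. A batch of other arrays stays open, and no biological explanation was tested.

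Of the changes common to the Tet1 and Sin3A knockdowns, 642 probe sets went the same way. Shuffles matched for signal level had a mean of 332 and a highest value of 375 in 1000, so brighter probe sets account for part of the overlap but not for all of it. The lower Sin3a level in the Tet1 knockdowns might carry part of it. For 228 of the 642 the mean Tet1 effect exceeded the Sin3A effect by over 2 standard errors, which argues against this route as their whole source. A part played by it stays open for them. The 642 were picked for passing with both Tet1 shRNAs, which favours large Tet1 effects, and the sets appear to have been normalized separately. Over the other 413, with Sin3a itself set aside, the median ratio of the Tet1 to the Sin3A effect was 0.954, but these were picked for passing in both knockdowns. Over all Sin3A calls, opposite changes included, the slope of the Tet1 mean on the Sin3A effect was 0.197, and the ratio for Sin3a itself was 0.164. The slope does not describe the 413 alone, and a response need not be proportional. Neither the slope nor the median ratio decides the question, so this route stays open for the 413 as well. A response to the control hairpin that both scrambled groups share may also raise the overlap, and the 319 opposite calls do not exclude it, so a shared function of Tet1 and Sin3A stays a hypothesis.

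Other splits of the same arrays were counted for each result. For Tet1 shRNA 4 (2459 probe sets), Tet1 shRNA 5 (2934) and Sin3A (5261) the 10 splits are too few for a share under 0.05, with 1 split of 10 as large in each and 0 in the highest other. For the list counts of both Tet1 shRNAs other splits gave as many, so chance is not excluded for them. These were 5 lists for shRNA 4 (4 of 10 splits as large, highest other 9) and 4 for shRNA 5 (5 of 10, highest other 6). For the 5 lists of Sin3A (1 of 10, highest other 4) the splits are again too few. Among 100 drawn splits, only the real 1 was as large for the calls shared by the Tet1 shRNAs (1868, highest other 1727), and for the difference between the effects (4241, highest other 3319). Mixing scrambled with knockdown arrays widens the spread within groups, so low counts in mixed splits were largely set in advance. Chance is therefore not called excluded for these 2 counts. The splits also do not part the knockdown from a difference between cultures. For the overlap (642, highest other 0, 1 of 100 as large) the splits decide nothing, since 0 of the other splits had calls for both Tet1 shRNAs and for Sin3A. The split with 1727 kept the 3 scrambled arrays together, and the remaining splits gave 0 shared calls. The split with 3319 left the Sin3A groups whole, and splits that broke up both sets gave at most 82 for the difference. For the 5 lists of the difference 24 of 100 splits were as large (highest other 9), so chance is not excluded.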
